A study of Mus musculus with 8 samples.

How the data were processed

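Expression was measured with Affymetrix arrays in total RNA of mouse peritoneal macrophages. Per the labels' protocols, cells obtained by peritoneal lavage were kept overnight in culture before treatment with recombinant HRG, RNA was extracted with a column kit, and 250 ng per sample was amplified into biotin-labelled sense-strand cDNA. Per the submitters' processing notes, Affymetrix Expression Console, RMA and limma were used. The deposited values are on a log2 scale, and the authors made them by RMA, which corrects the background, quantile-normalizes the arrays and summarises the probes of each row, per the submitters' processing notes. Their versions, the genome build and the source of the recombinant protein are not given in the sources used here. The 8 arrays had medians between 7.18 and 7.29 and lower quartiles between 5.85 (Basal_6h replicate 1) and 6.00 (Basal_24h replicate 1), so their distributions were close but not identical.

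The value table held 28853 rows, of which 21789 were paired with 1 gene symbol, 1621 with several and 5443 with none in the platform annotation. Symbols were looked up by gene ID in a RefSeq table of assembly GRCm38.p6, used only for names, which matched 21698 of the rows with 1 symbol and changed 0 symbols. Rows with several symbols or none were left out of the tests of genes. For the 998 genes with several rows, the row with the highest mean over the 8 arrays was used, which left 19939 genes. No array was left out of the reported results, and groups were taken from the sample titles.

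Differences were computed in R 4.3.3 with limma 3.58.1. A model with 1 coefficient per group was fitted to all 8 arrays (4 residual degrees of freedom, prior degrees of freedom 7.81), followed by contrasts.fit and eBayes. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 19939 genes of a comparison, with a threshold of 0.05. The 5 comparisons were HRG against basal at 6 h and at 24 h, the difference of these effects, and 24 h against 6 h in basal and in HRG samples. Reported errors are standard errors from the moderated fit, and levels are means ± SD of 2 arrays.

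Gene lists for 32 pathways and cell types were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 853 list entries, 773 were measured, 12 of them through an older name. Each list was tested against all other genes with camera (preset correlation 0.01), with camera under an estimated correlation and with fry as alternatives, and p-values were adjusted over the 32 lists of a comparison. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Counts "adjusted over the list alone" use the members of a list as the family of tests.

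Genes were named by rule: the 12 largest changes in each direction among those past the threshold for HRG against basal at each time, the 6 largest for the difference of the effects, the 8 largest for the basal time course, and up to 4 members of each list. Predicted genes, clone names, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out of the ranking but not of the tests. In addition, 18 genes were reported for HRG against basal whether or not they passed.

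The fit was tested on simulated data: in 20 simulated sets of 19939 genes per comparison, 200 genes were changed by known folds. At 6 h, 65.5% of 1.5-fold and 98.6% of 2-fold changes were recovered, and 5.15% of the calls were false. The simulated values had independent normal noise, with spreads drawn from the prior of the fit. The false share therefore follows from the assumptions of the model and is not an error rate of the real calls. The alternatives tried were the replicate number as a block, eBayes with trend and robust, renewed quantile normalization, centring of each array on its median, dropping the dimmest 30% of genes, testing every row, averaging the rows of a gene, a minimum fold of 1.5, a fit on only the 4 arrays compared, and leaving out each array in turn. The lower quartile of each array as a covariate was added after seeing the data.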

Results

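Transcript levels were measured in peritoneal macrophages of C57/Bl6 mice that had been cultured with or without recombinant histidine-rich glycoprotein (HRG), a plasma protein that binds heparan sulphate, zinc and haem. Cells of 10 mice had been pooled, and samples were collected after 6 h or 24 h with HRG at 1 µg/ml or without it (basal). Each of the 4 groups held 2 samples, each on its own Affymetrix array, for 8 arrays in all. Within groups, the 28853 values of the replicate arrays correlated at r = 0.996 in basal samples at 6 h, 0.998 in HRG samples at 6 h, 0.997 in basal samples at 24 h and 0.997 in HRG samples at 24 h, across rows of the array, which are not independent. The first principal component (44.5% of the variance) separated the 24 h samples from the 6 h samples, and the second (18.8%) separated HRG from basal samples at 24 h. All samples came from 1 pool of macrophages, and nothing states how far the replicates were handled apart. The p-values below therefore measure only the spread between these samples, which may be technical, and the number of arrays limits precision. Differences are given on the log2 scale as HRG minus basal, or 24 h minus 6 h, with the standard error of the limma fit and n = 2 arrays per group, and "rose" and "fell" are used for genes past an adjusted p of 0.05.

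The comparison at 6 h asked which transcripts HRG altered early. Transcripts of some receptors for dying cells and particles rose: Mertk, a receptor kinase for apoptotic cells, by 0.81 ± 0.10 (1.76-fold, adjusted p = 0.0045), Itgb5, an integrin subunit, by 0.84 ± 0.10, Stab1, the scavenger receptor stabilin-1, by 0.74 ± 0.10, and Vsig4, a complement receptor, by 0.79 ± 0.15. Olr1, a receptor for oxidised lipoprotein, rose 2.84-fold (1.51 ± 0.10, adjusted p = 0.00010), from 10.62 ± 0.12 to 12.13 ± 0.067 (mean log2 level ± SD, n = 2). Transcripts of some inflammatory cytokines fell: Il12b, the p40 subunit shared by IL-12 and IL-23, changed by -1.20 ± 0.15 (2.29-fold lower, adjusted p = 0.0035), Il6 by -0.94 ± 0.13, Csf2 by -0.94 ± 0.19 and Il23a by -0.79 ± 0.13. Ddit3, the transcription factor CHOP (-1.19 ± 0.11, adjusted p = 0.00092), and Asns, asparagine synthetase (-1.09 ± 0.13, adjusted p = 0.0035), fell as well. The T cell receptor component Cd3g fell by 1.11 ± 0.21 beside them.

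Among the 12 largest increases at 6 h, Gatm, the first enzyme of creatine synthesis, led with 1.56 ± 0.12, adjusted p = 0.00022. It was followed after Olr1 by the G protein subunit Gna15 (1.07 ± 0.13), the ecto-5'-nucleotidase Nt5e (1.01 ± 0.10), the UDP receptor P2ry6 (0.99 ± 0.099), Fam13a (0.93 ± 0.15), Tmem37 (0.87 ± 0.10), the membrane-bound transcription factor Creb3l2 (0.87 ± 0.13), the actin regulator Carmil1 (0.86 ± 0.10), Itgb5, the growth factor Tgfb2 (0.83 ± 0.13) and Mertk. The 12 largest decreases were Mospd4 (-1.46 ± 0.13), Fam171b (-1.46 ± 0.20), Il12b, Ddit3, the cystathionine-cleaving enzyme Cth (-1.18 ± 0.19), the eIF2α phosphatase subunit Ppp1r15a (-1.17 ± 0.13), the amino acid transporter Slc7a5 (-1.15 ± 0.14), Cd3g, the growth arrest gene Gadd45a (-1.11 ± 0.15), the glutathione-degrading enzyme Chac1 (-1.09 ± 0.12), Asns and the glycerol channel Aqp9 (-1.07 ± 0.13). Adjusted p of these 24 genes lay between 0.00010 for Olr1 and 0.029 for Cd3g.

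Gene lists fixed before the data were examined showed which groups moved at 6 h. In the list of complement, Fc receptors and phagocytic receptors, 4 of 34 rose, 0 fell and 30 did not pass (9 and 0 adjusted over the list alone), with a median of 0.10. For the phagocytic receptor list, camera gave adjusted p = 1.0e-06, and adjusted p = 0.43 with an estimated correlation. In the list of inflammatory cytokines and chemokines, 0 of 36 rose, 6 fell and 30 did not pass (1 and 11 adjusted over the list alone), with a median of -0.12. For the cytokine and chemokine list, camera gave adjusted p = 9.8e-06, and adjusted p = 0.43 with an estimated correlation. The cytokine and chemokine median (-0.12) ran from -0.18 to -0.12 without single arrays. In the overlapping list of classical (M1) activation markers, 0 of 22 rose, 6 fell and 16 did not pass (4 and 10 adjusted over the list alone), with Cd40, the receptor for CD40 ligand, at -0.71 ± 0.13. For the classical activation list, camera gave adjusted p = 0.00022, and adjusted p = 0.43 with an estimated correlation. The classical activation median (-0.16) ran from -0.26 to -0.11 without single arrays. Of the NF-κB targets, 0 of 28 rose, 3 fell and 25 did not pass (0 and 6 adjusted over the list alone), with the maturation marker Cd83 at -0.69 ± 0.10 and Traf1 at -0.66 ± 0.11. For the NF-κB list, camera gave adjusted p = 5.3e-07, and adjusted p = 0.45 with an estimated correlation. Of the alternative (M2) activation markers, 4 of 28 rose, 1 fell and 23 did not pass (6 and 4 adjusted over the list alone): Stab1, the arginine-degrading enzyme Arg1 (0.70 ± 0.097), the transglutaminase Tgm2 (0.64 ± 0.11) and the β-glucan receptor Clec7a (0.63 ± 0.10) rose, and Klf4 fell by 0.57 ± 0.12. For the alternative activation list, camera gave adjusted p = 0.038, and adjusted p = 0.43 with an estimated correlation. That alternative activation call was lost without 4 of the 8 single arrays, and over the 8 the median (0.092) ran from 0.084 to 0.17. Of the markers of resident large peritoneal macrophages, 5 of 24 rose, 1 fell and 18 did not pass (5 and 1 adjusted over the list alone), with Nt5e, Tgfb2 and Vsig4 higher and the clotting factor F5 lower at -0.79 ± 0.12. For the resident macrophage list, camera gave adjusted p = 0.00049, and adjusted p = 0.43 with an estimated correlation. That resident macrophage call was lost without 1 of the 8 single arrays, and over the 8 the median (0.12) ran from 0.11 to 0.15. In the interferon-stimulated list, 0 of 32 rose, 0 fell and 32 did not pass (0 and 0 adjusted over the list alone), and its median was 0.14. For the interferon list, camera gave adjusted p = 0.00038, and adjusted p = 0.64 with an estimated correlation. That interferon call was lost without 2 of the 8 single arrays, and over the 8 the median (0.14) ran from 0.083 to 0.20.

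The lists of lymphocyte markers had medians below 0 with HRG at 6 h, though few of their genes passed. Of the B cell markers, 0 of 24 rose, 1 fell and 23 did not pass (0 and 7 adjusted over the list alone), with a median of -0.28 and the antigen receptor component Cd79b at -0.59 ± 0.12. For the B cell list, camera gave adjusted p = 2.3e-09, and adjusted p = 0.43 with an estimated correlation. Of the T cell and NK cell markers, 0 of 27 rose, 2 fell and 25 did not pass (0 and 7 adjusted over the list alone), with a median of -0.22 and Cd28 at -0.60 ± 0.11. For the T cell and NK cell list, camera gave adjusted p = 3.5e-08, and adjusted p = 0.43 with an estimated correlation. The T cell and NK cell median (-0.22) ran from -0.35 to -0.13 without single arrays. Beside them, of the antigen presentation genes, 0 of 21 rose, 2 fell and 19 did not pass (0 and 3 adjusted over the list alone), with Cd80 at -0.51 ± 0.094. For the antigen presentation list, camera gave adjusted p = 0.0085, and adjusted p = 0.50 with an estimated correlation. That antigen presentation call was lost without 1 of the 8 single arrays, and over the 8 the median (-0.086) ran from -0.13 to -0.043. Of the dendritic cell markers, 0 of 21 rose, 2 fell and 19 did not pass (0 and 4 adjusted over the list alone), with Dpp4 at -0.58 ± 0.11 and the chemokine receptor Ccr7 at -0.54 ± 0.11. For the dendritic cell list, camera gave adjusted p = 0.0025, and adjusted p = 0.43 with an estimated correlation. That dendritic cell call was lost without 1 of the 8 single arrays, and over the 8 the median (-0.083) ran from -0.12 to -0.069.

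Stress and signalling genes moved unevenly at 6 h. In the list of unfolded protein response and heat shock genes, 0 of 28 rose, 6 fell and 22 did not pass (1 and 7 adjusted over the list alone), with Ddit3, Chac1, Asns and the pseudokinase Trib3 (-1.06 ± 0.12) lower. Its median was 0.099 and its mean -0.15, opposite in sign, and the list was not called (camera adjusted p = 0.10). Of the apoptosis and p53 targets, 0 of 26 rose, 3 fell and 23 did not pass (0 and 7 adjusted over the list alone), with Gadd45a and Gadd45b (-0.54 ± 0.11) lower. The median of that list was 0.00058, while its mean was -0.13 and its test pointed down. For the apoptosis list, camera gave adjusted p = 0.024, and adjusted p = 0.46 with an estimated correlation. That apoptosis call was lost without 1 of the 8 single arrays, and over the 8 the median (0.00058) ran from -0.035 to 0.030. Of the immediate early and MAPK feedback genes, 0 of 32 rose, 1 fell and 31 did not pass (1 and 6 adjusted over the list alone). For the immediate early list, camera gave adjusted p = 0.0016, and adjusted p = 0.46 with an estimated correlation. The immediate early median (-0.081) ran from -0.14 to -0.066 without single arrays. Of the hypoxia and glycolysis genes, 0 of 26 rose, 1 fell and 25 did not pass (3 and 2 adjusted over the list alone), and Ndrg1 was the member that fell, at -0.94 ± 0.16, although the median was 0.15 and the test pointed up. For the hypoxia list, camera gave adjusted p = 0.024, and adjusted p = 0.64 with an estimated correlation. That hypoxia call was lost without 2 of the 8 single arrays, and over the 8 the median (0.15) ran from 0.11 to 0.16. Among Toll-like receptors and inflammasome genes, Tlr8 rose by 0.71 ± 0.12 and the Toll adaptor Ticam2 fell by 0.96 ± 0.12. Among clotting genes, tissue factor, F3, rose by 0.65 ± 0.12, and among angiogenic factors Fgf2 rose by 0.75 ± 0.11. The metallothionein Mt2 (-0.53 ± 0.11), the matrix protease Mmp3 (-0.56 ± 0.11), the adhesion molecule Vcam1 (-0.58 ± 0.11) and the thymidylate synthase Tyms (-0.55 ± 0.098) fell, and Alas1, which starts haem synthesis, rose by 0.53 ± 0.097.

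Altogether, 86 of 19939 genes rose and 163 fell at 6 h, 4 and 18 of them at least 2-fold, by limma with Benjamini-Hochberg adjustment, and 2194 genes had an unadjusted p under 0.05. The counts rested on single arrays: 31 rose and 31 fell without Basal_6h replicate 1, 44 and 145 without Basal_6h replicate 2, 18 and 55 without HRG_6h replicate 1, 10 and 11 without HRG_6h replicate 2, and 49 and 81 without HRG_24h replicate 1 or without HRG_24h replicate 2, which lend their spread to the fit. Camera called 5 lists up and 9 down of 32, and with an estimated correlation 0 were called (smallest adjusted p = 0.43), as with fry (smallest adjusted p = 0.098).

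The comparison at 24 h asked which transcripts differed after prolonged contact with HRG. The 3 subunits of complement C1q, which opsonises dying cells and immune complexes, rose: C1qc by 2.36 ± 0.19 (5.15-fold, adjusted p = 5.2e-05), C1qa by 1.87 ± 0.16 (3.65-fold) and C1qb by 1.66 ± 0.13 (3.16-fold). The complement receptor Vsig4 rose 4.30-fold (2.10 ± 0.15, adjusted p = 4.5e-05), from 8.96 ± 0.20 to 11.06 ± 0.042, and Mrc1, the mannose receptor, rose 2.77-fold (1.47 ± 0.12, adjusted p = 5.2e-05). Several detoxifying enzymes that the transcription factor NRF2 controls fell: Nqo1, a quinone reductase, was 5.33-fold lower (-2.41 ± 0.16, adjusted p = 2.9e-05), Me1, malic enzyme, changed by -1.31 ± 0.15, Srxn1, sulfiredoxin, by -1.23 ± 0.099 and Gclc, the catalytic subunit of glutathione synthesis, by -1.20 ± 0.11. The antigen presentation gene H2-Aa (1.10 ± 0.16) and the B cell marker Cd79a (0.98 ± 0.16) rose.

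**Figure D1:**
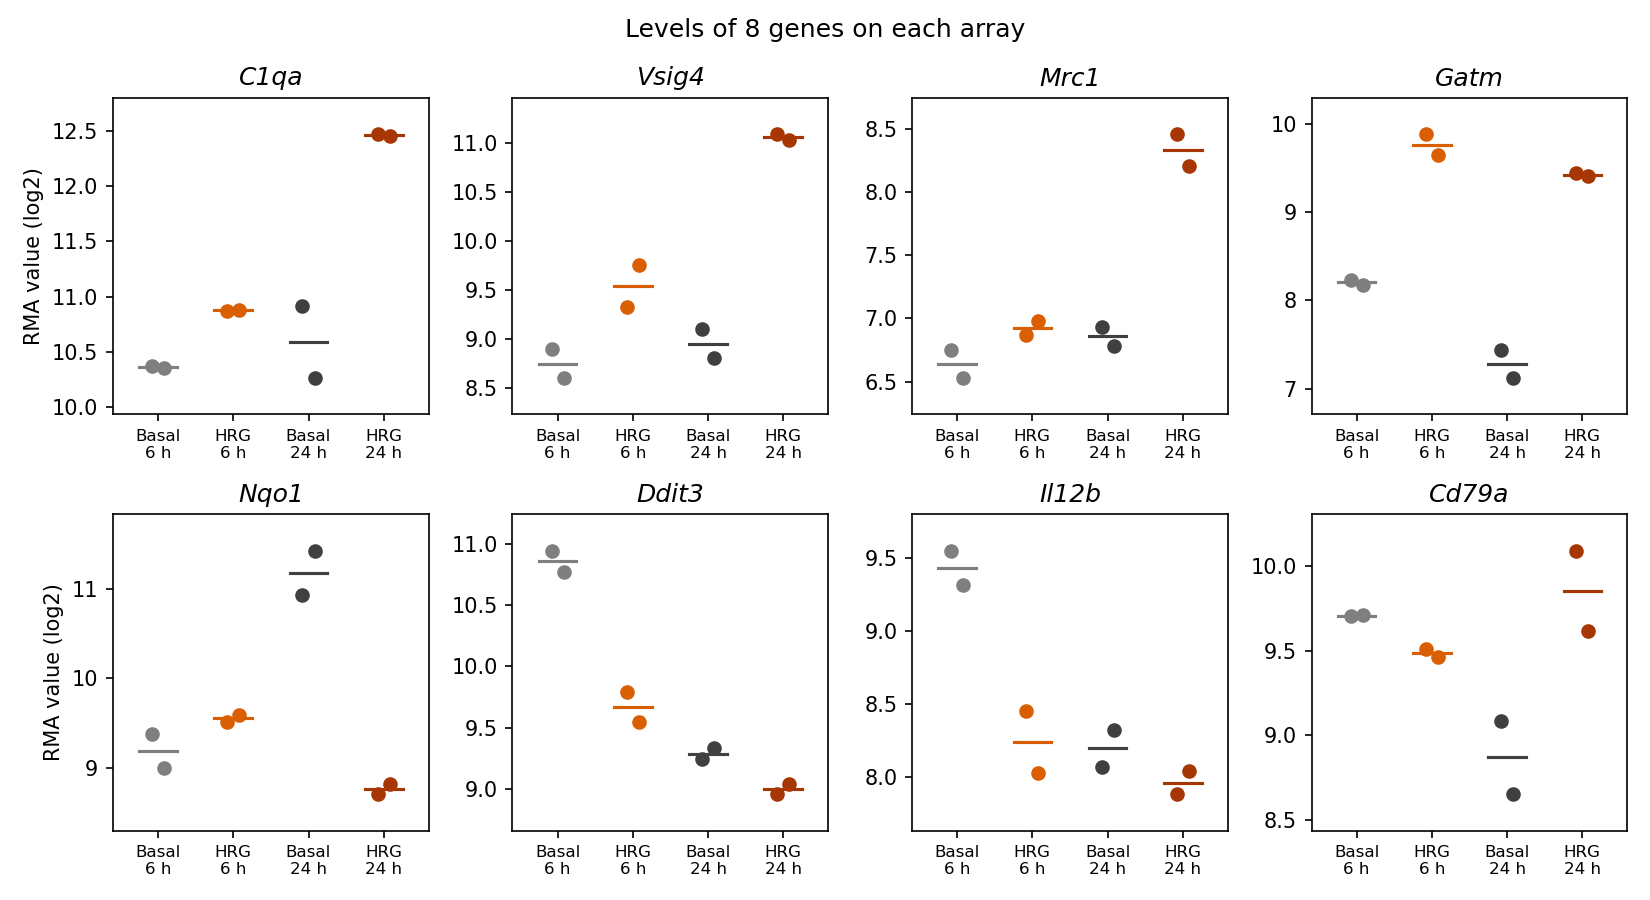
RMA values (log2) of 8 genes on each of the 8 arrays. Points are arrays, horizontal lines are group means (n = 2), and the groups are basal and HRG samples at 6 h and 24 h. C1qa, Vsig4 and Mrc1 lie higher on both HRG arrays at 24 h than on both basal arrays, and Nqo1 lies lower on both.

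The 12 largest increases at 24 h were C1qc, Gatm (2.15 ± 0.12), Vsig4, C1qa, C1qb, the secreted protein Olfml3 (1.63 ± 0.13), Ifitm6 (1.52 ± 0.14), the serpin Serpinb10 (1.501 ± 0.19), Nxpe5 (1.496 ± 0.20), Mrc1, the myeloid receptor Trem1 (1.44 ± 0.12) and the matrix protein Sparc (1.44 ± 0.17). The 12 largest decreases were Nqo1, Il1f9, which encodes IL-36γ (-2.29 ± 0.14), the glycine transporter Slc6a9 (-2.14 ± 0.16), Pir (-1.72 ± 0.12), the iron exporter Slc40a1 (-1.67 ± 0.30), Eid3 (-1.65 ± 0.16), the aldo-keto reductase Akr1b8 (-1.58 ± 0.17), Tnfsf4, which encodes OX40 ligand (-1.41 ± 0.26, a dim gene), Treml4 (-1.40 ± 0.24), the carbonyl reductase Cbr3 (-1.34 ± 0.18), the glutathione transferase Gsta4 (-1.33 ± 0.25) and the epoxide hydrolase Ephx1 (-1.33 ± 0.14). Adjusted p of these 24 genes lay between 1.2e-05 for Gatm and 0.011 for Gsta4.

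In the list of complement, Fc receptors and phagocytic receptors at 24 h, 15 of 34 rose, 0 fell and 19 did not pass (22 and 1 adjusted over the list alone), with a median of 0.38. For the phagocytic receptor list, camera gave adjusted p = 1.1e-24, and adjusted p = 0.055 with an estimated correlation. Of the alternative (M2) activation markers, 7 of 28 rose, 0 fell and 21 did not pass (13 and 0 adjusted over the list alone), among them Mrc1, the eosinophil chemokine Ccl24 (1.41 ± 0.18), Tgm2 (0.94 ± 0.11) and Stab1 (0.74 ± 0.10). For the alternative activation list, camera gave adjusted p = 1.7e-15, and adjusted p = 0.055 with an estimated correlation. Of the markers of monocyte-derived and small peritoneal macrophages, 12 of 23 rose, 0 fell and 11 did not pass (15 and 0 adjusted over the list alone), among them the clotting factor F13a1 (1.42 ± 0.15), the folate receptor Folr2 (1.13 ± 0.12) and Ms4a4c (1.06 ± 0.16). For the small macrophage list, camera gave adjusted p = 4.5e-19, and adjusted p = 0.094 with an estimated correlation. Of the markers of resident large peritoneal macrophages, 5 of 24 rose, 2 fell and 17 did not pass (9 and 2 adjusted over the list alone), with Vsig4 and the phosphatidylserine receptor Timd4 (0.74 ± 0.11) higher and the endothelin receptor Ednrb (-0.81 ± 0.097) lower. For the resident macrophage list, camera gave adjusted p = 5.6e-05, and adjusted p = 0.15 with an estimated correlation. Of the negative regulators and anti-inflammatory mediators, 9 of 26 rose, 1 fell and 16 did not pass (14 and 1 adjusted over the list alone), with Socs2 at 0.71 ± 0.14 and the lipid receptor Trem2 at 0.67 ± 0.11. For the negative regulator list, camera gave adjusted p = 1.9e-11, and adjusted p = 0.10 with an estimated correlation.

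In the list of NRF2 and oxidative stress genes, 0 of 26 rose, 12 fell and 14 did not pass (0 and 15 adjusted over the list alone), with a median of -0.41. For the NRF2 list, camera gave adjusted p = 1.6e-17, and adjusted p = 0.13 with an estimated correlation. Of the LXR targets and lipid genes, 7 of 23 rose, 1 fell and 15 did not pass (10 and 3 adjusted over the list alone), with the fatty acid binding proteins Fabp5 (1.08 ± 0.13) and Fabp4 (0.79 ± 0.11), the desaturase Scd1 (1.05 ± 0.13) and Olr1 (1.02 ± 0.10) higher. For the LXR list, camera gave adjusted p = 4.4e-06, and adjusted p = 0.15 with an estimated correlation. The LXR median (0.094) ran from 0.085 to 0.15 without single arrays. Of the cholesterol biosynthesis genes, 1 of 20 rose, 0 fell and 19 did not pass (4 and 0 adjusted over the list alone), with Insig1 at 0.47 ± 0.11. For the cholesterol list, camera gave adjusted p = 1.5e-08, and adjusted p = 0.10 with an estimated correlation. Of the oxidative phosphorylation genes, 0 of 30 rose, 0 fell and 30 did not pass (0 and 0 adjusted over the list alone), with a median of 0.12. For the oxidative phosphorylation list, camera gave adjusted p = 0.00033, and adjusted p = 0.37 with an estimated correlation. That oxidative phosphorylation call was lost without 1 of the 8 single arrays, and over the 8 the median (0.12) ran from 0.050 to 0.16. In the list of unfolded protein response and heat shock genes, 0 of 28 rose, 2 fell and 26 did not pass (0 and 2 adjusted over the list alone), with Trib3 at -0.89 ± 0.12 and Asns at -0.75 ± 0.13. For the unfolded protein list, camera gave adjusted p = 0.0096, and adjusted p = 0.50 with an estimated correlation. That unfolded protein call was lost without 2 of the 8 single arrays, and over the 8 the median (-0.059) ran from -0.11 to -0.016.

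Some inflammatory and interferon genes rose at 24 h with HRG relative to basal samples. In the interferon-stimulated list, 7 of 32 rose, 0 fell and 25 did not pass (23 and 0 adjusted over the list alone), with a median of 0.40, and Gbp5 (0.93 ± 0.18), the antiviral GTPase Mx1 (0.84 ± 0.20), Ifi205 (0.84 ± 0.14) and Cmpk2 (0.75 ± 0.15) were the largest. For the interferon list, camera gave adjusted p = 4.7e-21, and adjusted p = 0.15 with an estimated correlation. The basal arrays differed, and the median of that list was 0.25 without Basal_24h replicate 2 and 0.63 without Basal_24h replicate 1. Of the inflammatory cytokines and chemokines, 8 of 36 rose, 0 fell and 28 did not pass (11 and 1 adjusted over the list alone), with the chemokines Ccl9 (0.75 ± 0.14) and Ccl22 (0.73 ± 0.13) and the cytokine Il18 (0.71 ± 0.14) among the largest beside Ccl24. Ccl22 and Ccl24 are also on the alternative activation list, and the cytokine genes Tnf, Il1b, Il6 and Il12b did not pass. For the cytokine and chemokine list, camera gave adjusted p = 0.0010, and adjusted p = 0.27 with an estimated correlation. That cytokine and chemokine call was lost without 1 of the 8 single arrays, and over the 8 the median (0.039) ran from -0.0070 to 0.18. Of the classical (M1) activation markers, 2 of 22 rose, 0 fell and 20 did not pass (5 and 2 adjusted over the list alone), with the costimulatory molecule Cd86 at 0.52 ± 0.10 and Irf1 at 0.41 ± 0.10. For the classical activation list, camera gave adjusted p = 0.0095, and adjusted p = 0.37 with an estimated correlation. That classical activation call was lost without 2 of the 8 single arrays, and over the 8 the median (0.16) ran from 0.11 to 0.18. Another row of the array for Irf1, dimmer and not used in the fit, gave -0.061. Of the NF-κB targets, 4 of 28 rose, 0 fell and 24 did not pass (5 and 0 adjusted over the list alone), with Marcksl1 at 0.82 ± 0.17 and Cd83 at 0.53 ± 0.10. For the NF-κB list, camera gave adjusted p = 0.0062, and adjusted p = 0.50 with an estimated correlation. That NF-κB call was lost without 1 of the 8 single arrays, and over the 8 the median (0.041) ran from 0.026 to 0.11. Of the Toll-like receptors and inflammasome genes, 3 of 30 rose, 0 fell and 27 did not pass (6 and 0 adjusted over the list alone), with the adaptor Pycard at 1.05 ± 0.15 and Tlr8 at 0.84 ± 0.12. For the Toll-like receptor list, camera gave adjusted p = 0.00013, and adjusted p = 0.27 with an estimated correlation. The Toll-like receptor median (0.069) ran from 0.031 to 0.15 without single arrays. Of the immediate early genes, 3 of 32 rose, 2 fell and 27 did not pass (3 and 2 adjusted over the list alone), with Fos at 0.94 ± 0.095 and Fosl1 at -0.77 ± 0.16. For the immediate early list, camera gave adjusted p = 0.029, and adjusted p = 0.49 with an estimated correlation. That immediate early call was lost without 2 of the 8 single arrays, and over the 8 the median (0.10) ran from 0.041 to 0.12. Without Basal_24h replicate 1 the test pointed down (median 0.041, adjusted p = 0.93).

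Some markers of B cells, mast cells and dendritic cells rose at 24 h. Of the B cell markers, 11 of 24 rose, 0 fell and 13 did not pass (19 and 1 adjusted over the list alone), with a median of 0.50, and the immunoglobulin joining chain Jchain (1.30 ± 0.10, a dim gene), Cd79a, Fcmr (0.81 ± 0.17) and Ms4a1, which encodes CD20 (0.80 ± 0.15), were the largest. For the B cell list, camera gave adjusted p = 1.7e-17, and adjusted p = 0.10 with an estimated correlation. Beside them, of the antigen presentation genes, 6 of 21 rose, 0 fell and 15 did not pass (12 and 1 adjusted over the list alone), with H2-Aa and the invariant chain Cd74 (1.00 ± 0.12) the largest, genes that B cells also express. For the antigen presentation list, camera gave adjusted p = 1.1e-10, and adjusted p = 0.10 with an estimated correlation. The antigen presentation median (0.26) ran from 0.23 to 0.44 without single arrays. Of the mast cell and granulocyte markers, 6 of 30 rose, 0 fell and 24 did not pass (8 and 1 adjusted over the list alone), with the mast cell protease Cpa3 at 0.97 ± 0.18 and the receptor Mrgprb1 at 0.88 ± 0.15. For the mast cell and granulocyte list, camera gave adjusted p = 7.6e-05, and adjusted p = 0.10 with an estimated correlation. The mast cell and granulocyte median (0.078) ran from 0.069 to 0.12 without single arrays. Of the dendritic cell markers, 2 of 21 rose, 0 fell and 19 did not pass (10 and 0 adjusted over the list alone), with Ly6d at 0.42 ± 0.10. For the dendritic cell list, camera gave adjusted p = 7.4e-06, and adjusted p = 0.10 with an estimated correlation. Of the T cell and NK cell markers, 0 of 27 rose, 0 fell and 27 did not pass (0 and 0 adjusted over the list alone), with a median of 0.055 (camera adjusted p = 0.060). Of these markers, 20 had a mean level below the median of all genes, and the 7 above it had a median difference of 0.25. Of the cell cycle genes, 5 of 41 rose, 0 fell and 36 did not pass (13 and 0 adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at 0.81 ± 0.12 and the cyclin Ccna2 at 0.78 ± 0.11. For the cell cycle list, camera gave adjusted p = 1.0e-12, and adjusted p = 0.055 with an estimated correlation.

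Genes of the cell surface and the matrix differed at 24 h as well. In the matrix remodelling list, 8 of 29 rose, 0 fell and 21 did not pass (13 and 0 adjusted over the list alone), with the protease inhibitors Timp3 (1.18 ± 0.11) and Timp1 (0.94 ± 0.093) and the protease Mmp9 (0.80 ± 0.097) higher. For the matrix remodelling list, camera gave adjusted p = 6.2e-09, and adjusted p = 0.10 with an estimated correlation. The matrix remodelling median (0.26) ran from 0.11 to 0.26 without single arrays. Of the migration receptors and integrins, 5 of 27 rose, 1 fell and 21 did not pass (10 and 2 adjusted over the list alone), with the chemokine receptor Cxcr4 at 1.00 ± 0.090 and the semaphorin receptor Nrp1 at -0.91 ± 0.15. For the migration list, camera gave adjusted p = 2.9e-06, and adjusted p = 0.091 with an estimated correlation. The migration median (0.13) ran from 0.12 to 0.21 without single arrays. Of the coagulation and fibrinolysis genes, 5 of 24 rose, 2 fell and 17 did not pass (6 and 2 adjusted over the list alone), with tissue factor, F3, at 0.81 ± 0.12 and the protein C receptor Procr at -1.31 ± 0.14. For the coagulation list, camera gave adjusted p = 0.0062, and adjusted p = 0.10 with an estimated correlation. The coagulation median (0.055) ran from 0.026 to 0.095 without single arrays.

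Other lists that were not called at 24 h also held changed genes. Of the angiogenic growth factors and inhibitors, 1 of 26 rose, 2 fell and 23 did not pass (4 and 3 adjusted over the list alone), with Hgf at 0.80 ± 0.14 and the dim gene Vegfd at -0.45 ± 0.096. Of the iron and haem genes, 2 of 27 rose, 2 fell and 23 did not pass (3 and 3 adjusted over the list alone), with Slc40a1 lower and the transferrin gene Trf at 0.69 ± 0.11. Of the metallothioneins and metal transporters, 0 of 22 rose, 3 fell and 19 did not pass (0 and 3 adjusted over the list alone), with the zinc importers Slc39a4 at -0.78 ± 0.15 and Slc39a10 at -0.65 ± 0.12. Of the lysosomal genes, 1 of 27 rose, 2 fell and 24 did not pass (4 and 2 adjusted over the list alone), with the acid lipase Lipa at -0.72 ± 0.13. Of the apoptosis and p53 targets, 1 of 26 rose, 2 fell and 23 did not pass (3 and 5 adjusted over the list alone), with Sesn1 at 0.91 ± 0.11 and the death receptor Fas at -0.72 ± 0.11. Of the hypoxia and glycolysis genes, 1 of 26 rose, 0 fell and 25 did not pass (1 and 0 adjusted over the list alone), with Aldoc at 0.68 ± 0.10, and of the mesothelial, fibroblast and endothelial markers, 1 of 30 rose, 0 fell and 29 did not pass (3 and 0 adjusted over the list alone), with Gpm6a at 0.59 ± 0.10. Camera adjusted p of these 7 lists lay between 0.067 for the lysosomal genes and 0.70 for the iron and haem genes.

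**Figure D2:**
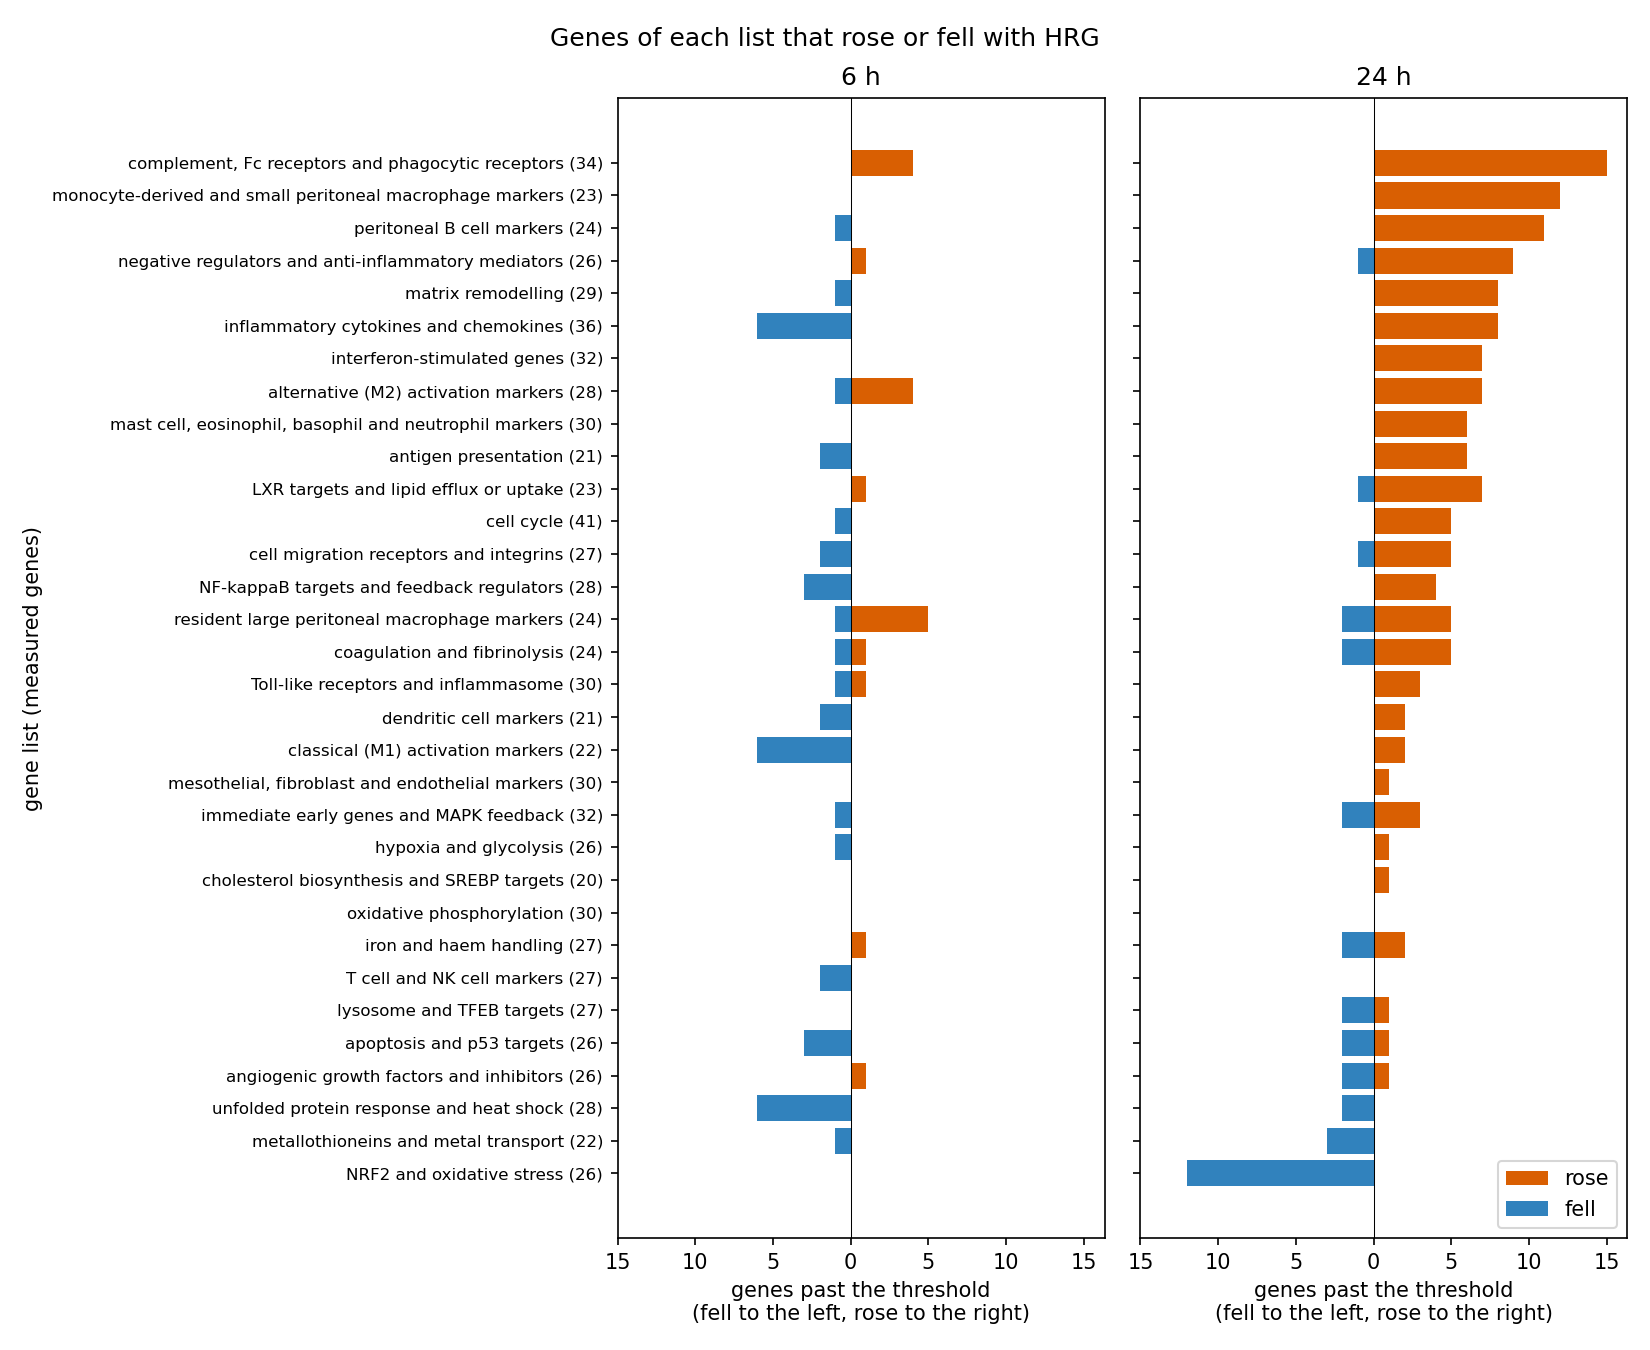
Number of genes of each of the 32 fixed lists that rose (right, orange) or fell (left, blue) with HRG, at 6 h and at 24 h. The number of measured genes of a list stands in brackets. The bars for phagocytic receptors reach 4 genes at 6 h and 15 at 24 h, and those for NRF2 genes 0 and 12 to the left.

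Altogether, 485 genes rose and 209 fell at 24 h, 66 and 36 of them at least 2-fold, and 2531 had an unadjusted p under 0.05. The counts were 110 and 72 without HRG_24h replicate 1, 313 and 91 without HRG_24h replicate 2, and 214 and 84 without Basal_24h replicate 2. Genes that rose made up 69.9% of those past the threshold, and 58.8% with the lower quartile of each array as a covariate, a setting chosen after seeing the data. Camera called 22 lists up and 2 down, fry called 16, and with an estimated correlation 0 were called (smallest adjusted p = 0.055).

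Genes of prior interest were reported at both times whether or not they passed. Hrg itself was at -0.031 ± 0.11 at 6 h and -0.11 ± 0.11 at 24 h, neither past the threshold. The angiogenic factors Pgf (0.21 ± 0.092 and 0.18 ± 0.092) and Vegfa (0.054 ± 0.10 and 0.053 ± 0.10) and the inhibitor Thbs1 (-0.022 ± 0.091 and -0.028 ± 0.091) did not pass at either time. The cytokines Tnf (-0.47 ± 0.15 and -0.024 ± 0.15), Il1b (0.14 ± 0.11 and 0.15 ± 0.11), Il10 (-0.054 ± 0.20 and 0.75 ± 0.20) and Ifnb1 (0.096 ± 0.11 and -0.13 ± 0.11) did not pass either. The same held for Nos2, the inducible nitric oxide synthase (0.32 ± 0.11 and 0.22 ± 0.11), the scavenger receptor Cd163 (-0.033 ± 0.095 and 0.18 ± 0.095), the chemokine Cxcl9 (0.39 ± 0.13 and 0.17 ± 0.13), haem oxygenase, Hmox1 (0.11 ± 0.098 and -0.091 ± 0.098), and the metallothionein Mt1 (-0.21 ± 0.11 and 0.099 ± 0.11). Il6 (-0.50 ± 0.13, adjusted p = 0.072), Il12b (-0.23 ± 0.15, adjusted p = 0.63) and Arg1 (0.27 ± 0.097, adjusted p = 0.23) passed at 6 h and not at 24 h, while Mrc1 (0.29 ± 0.12, adjusted p = 0.38) and Ccl22 (-0.41 ± 0.13, adjusted p = 0.20) passed at 24 h and not at 6 h. The difference between the effects at the 2 times passed for Il12b, Mrc1 and Ccl22, and did not pass for Il6 and Arg1. On simulated data of the same design, with independent noise and 200 changed genes, the fit recovered on average 99% of 2-fold and 59.1% of 1.5-fold changes at 24 h. Recovery depends on how many genes change, and the simulations of both times had the same settings. The shares are therefore a rough guide, and smaller changes of these genes are not ruled out. The standard errors of Il10 (0.20) and Tnf (0.15) exceeded the median of 0.11 over all genes, so for them larger changes are not ruled out either.

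The difference between the HRG effects at 24 h and 6 h was tested as an interaction. It was largest for Nqo1 (-2.78 ± 0.23, adjusted p = 0.00043), Il1f9 (-2.50 ± 0.19), Treml4 (-1.96 ± 0.34), Eid3 (-1.88 ± 0.23), Pir (-1.77 ± 0.18) and Slc6a9 (-1.74 ± 0.22) in the negative direction. In the positive direction it was largest for Ifitm6 (2.13 ± 0.20, adjusted p = 0.00082), C1qc (1.78 ± 0.27), Cd3g (1.48 ± 0.30), Adgre4, an adhesion receptor of myeloid cells (1.48 ± 0.21), Mrgprb2, a mast cell receptor (1.45 ± 0.22), and Scd1 (1.44 ± 0.19). The effect differed for Mrc1 as well (1.19 ± 0.17, adjusted p = 0.0065), whereas for Gatm (0.59 ± 0.17, adjusted p = 0.14) and Mertk (-0.30 ± 0.15, adjusted p = 0.49) the difference did not pass. In the B cell list the difference passed for 14 of 24 genes, all positive, with a median of 0.86. For the B cell list, camera gave adjusted p = 4.3e-24, and adjusted p = 0.10 with an estimated correlation. In the antigen presentation list for 5 of 21. For the antigen presentation list, camera gave adjusted p = 1.8e-12, and adjusted p = 0.10 with an estimated correlation. The antigen presentation median (0.32) ran from 0.27 to 0.52 without single arrays. In the NRF2 list it passed for 10 of 26, all negative, with a median of -0.40. For the NRF2 list, camera gave adjusted p = 7.6e-15, and adjusted p = 0.17 with an estimated correlation.

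Altogether, the effect was higher at 24 h for 204 genes and lower for 90, by limma with Benjamini-Hochberg adjustment, and 2196 genes had an unadjusted p under 0.05. Genes past the threshold in the same direction at both times numbered 43 higher, against 2.09 for independent lists, and 16 lower, against 1.71. Both comparisons use the same estimate of spread for a gene, so genes of small spread can pass at both times more often than independent lists would. Another 7 genes rose at one time and fell at the other, against 4.87. They were Cd83, Fam13a, Lrp8, Sema7a, Slc16a9, Stat4 and Tnfsf9, of which Lrp8, Sema7a, Slc16a9 and Stat4 were singled out after their values were seen. Fam13a, Lrp8 (0.62 ± 0.11 at 6 h, -1.05 ± 0.11 at 24 h) and Slc16a9 (0.69 ± 0.090 and -0.79 ± 0.090) went from higher to lower, and Cd83, Sema7a (-0.48 ± 0.092 and 0.54 ± 0.092), Stat4 (-0.56 ± 0.12 and 0.60 ± 0.12) and the cytokine gene Tnfsf9 (-0.57 ± 0.095 and 0.48 ± 0.095) from lower to higher. Across the 19939 genes, which are not independent replicates, the effects at 6 h and 24 h correlated at r = 0.106 (Spearman rho = 0.053). Leaving out 1 array moved r from 0.037 (without Basal_6h replicate 2) to 0.157 (without Basal_6h replicate 1). Across the 877 genes past the threshold at either time, they correlated at r = 0.276 (rho = 0.300). The counts of differing genes were 28 and 28 without HRG_24h replicate 1, 106 and 34 without HRG_24h replicate 2, 50 and 38 without HRG_6h replicate 2, 79 and 41 without HRG_6h replicate 1, 86 and 42 without Basal_24h replicate 2, 104 and 92 without Basal_6h replicate 1, and 265 and 139 without Basal_24h replicate 1. With the lower quartile of each array as a covariate, the share of higher genes went from 69.4% to 58.6%.

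**Figure D3:**
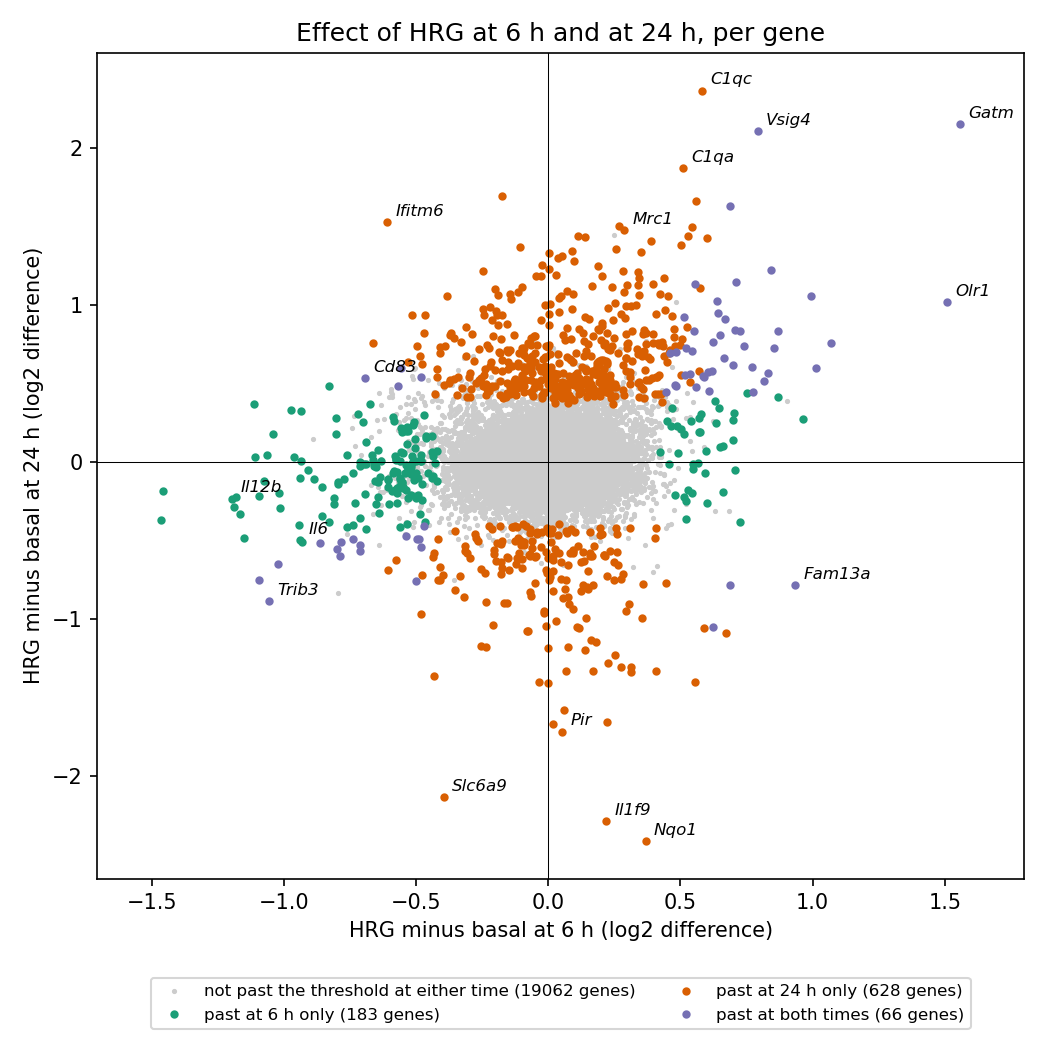
Effect of HRG at 24 h (vertical axis, log2 difference) against its effect at 6 h (horizontal axis, log2 difference) for each of the 19939 genes. Colours give the time at which a gene passed an adjusted p of 0.05. Gatm and Olr1 lie at the upper right, and Nqo1 and Il1f9 lie lowest, right of 0 on the horizontal axis.

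The comparison of 24 h with 6 h in basal samples gave the change over time in culture without HRG. Most interferon-stimulated transcripts fell: Rsad2, which encodes viperin, changed by -2.35 ± 0.13 (5.10-fold lower, adjusted p = 1.7e-06), Ifit3 by -2.09 ± 0.24, Cmpk2 by -1.89 ± 0.15 and Mx1 by -1.85 ± 0.20. Most glycolytic and hypoxia-responsive transcripts rose, with the aldolase Aldoc 3.69-fold higher (1.88 ± 0.10, adjusted p = 1.7e-06), the pyruvate dehydrogenase kinase Pdk1 at 1.56 ± 0.094 and the phosphofructokinase Pfkl at 1.29 ± 0.10. Several NRF2-controlled enzymes rose, among them Nqo1 (3.98-fold, 1.99 ± 0.16, adjusted p = 2.0e-05) and Srxn1 (0.98 ± 0.099). Most B cell markers fell, among them the transcription factors Ebf1 (-1.58 ± 0.17) and Spib (-1.51 ± 0.16).

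The 8 largest increases without HRG were Ephx1 (2.44 ± 0.14), the lipid transporter Abca9 (2.08 ± 0.11), Nqo1, the lectin receptor Clec4n (1.94 ± 0.13), Aldoc, Fam13a (1.76 ± 0.15), Slc40a1 (1.62 ± 0.30) and the lipoxygenase Alox5 (1.59 ± 0.091). The 8 largest decreases were the cholesterol hydroxylase Ch25h (-2.88 ± 0.13), Rsad2, Ifi206 (-2.28 ± 0.17), Tpbpa (-2.26 ± 0.17), Fam171b (-2.24 ± 0.20), Mmp3 (-2.15 ± 0.11), Ifit3 and Ifi213 (-2.01 ± 0.28). Of the interferon-stimulated genes, 0 of 32 rose, 26 fell and 6 did not pass (0 and 31 adjusted over the list alone), with a median of -0.82. For the interferon list, camera gave adjusted p = 4.5e-32, and adjusted p = 0.16 with an estimated correlation. Of the hypoxia and glycolysis genes, 22 of 26 rose, 1 fell and 3 did not pass (22 and 1 adjusted over the list alone), with a median of 0.63. For the hypoxia list, camera gave adjusted p = 1.4e-20, and adjusted p = 0.16 with an estimated correlation. Of the cholesterol biosynthesis genes, 9 of 20 rose, 0 fell and 11 did not pass (17 and 0 adjusted over the list alone), with squalene epoxidase, Sqle, at 1.08 ± 0.11. For the cholesterol list, camera gave adjusted p = 9.6e-12, and adjusted p = 0.16 with an estimated correlation. Of the NRF2 genes, 14 of 26 rose, 0 fell and 12 did not pass (15 and 0 adjusted over the list alone). For the NRF2 list, camera gave adjusted p = 1.4e-11, and adjusted p = 0.29 with an estimated correlation. Of the B cell markers, 0 of 24 rose, 17 fell and 7 did not pass (1 and 18 adjusted over the list alone). For the B cell list, camera gave adjusted p = 1.1e-15, and adjusted p = 0.16 with an estimated correlation. Beside the B cell markers, of the antigen presentation genes, 0 of 21 rose, 14 fell and 7 did not pass (1 and 16 adjusted over the list alone), with H2-Aa at -1.40 ± 0.16. For the antigen presentation list, camera gave adjusted p = 2.9e-14, and adjusted p = 0.16 with an estimated correlation. Of the inflammatory cytokines and chemokines, 2 of 36 rose, 13 fell and 21 did not pass (3 and 21 adjusted over the list alone), with the chemokine Cxcl10 at -1.66 ± 0.13. For the cytokine and chemokine list, camera gave adjusted p = 1.3e-09, and adjusted p = 0.16 with an estimated correlation. The cytokine and chemokine median (-0.35) ran from -0.40 to -0.23 without single arrays.

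Altogether, 758 genes rose and 1093 fell from 6 h to 24 h without HRG, and 4061 had an unadjusted p under 0.05. With HRG, 880 rose and 572 fell. In the basal comparison the counts were 568 and 600 without Basal_6h replicate 1, 373 and 751 without Basal_24h replicate 2, and 583 and 717 without Basal_24h replicate 1. In the HRG comparison they were 390 and 139 without HRG_6h replicate 1, 397 and 279 without HRG_6h replicate 2, 402 and 264 without HRG_24h replicate 1, and 472 and 162 without HRG_24h replicate 2. With the lower quartile of each array as a covariate, the share of higher genes among those past the threshold with HRG went from 60.6% to 50.1%. Camera called 17 lists without HRG and 14 with it, fry 13 and 8, and with an estimated correlation 0 in both.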

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

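Of the tests in this part, those of the B cell share, the macrophage share, the change over time and endotoxin, and the covariate for the spread of the arrays, were chosen only after the results were seen. The results below were singled out because the effect of HRG differed between 6 h and 24 h by the interaction test of limma, or because a signal appeared in rows that the tests of genes did not use. The effect was higher at 24 h for 204 genes and lower for 90.

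Among gene lists, 23 of 32 had a difference between the times past the threshold of camera, and 0 with an estimated correlation (smallest adjusted p = 0.10). The median difference was 0.86 for B cell markers, 0.29 for T cell and NK cell markers, 0.37 for dendritic cell markers, 0.087 for mast cell and granulocyte markers and 0.43 for monocyte-derived and small peritoneal macrophage markers. It was 0.34 for inflammatory cytokines and chemokines, 0.29 for NF-κB targets, 0.34 for classical markers, 0.30 for interferon-stimulated genes, 0.19 for immediate early genes and 0.13 for Toll-like receptors and inflammasome genes. It was 0.25 for alternative markers, 0.22 for negative regulators, 0.26 for complement and phagocytic receptors, 0.32 for antigen presentation, 0.21 for migration receptors, 0.15 for matrix remodelling and 0.19 for the cell cycle. It was 0.10 for oxidative phosphorylation, 0.17 for cholesterol biosynthesis, 0.019 for LXR targets, 0.067 for lysosomal genes and -0.40 for NRF2 genes, the list with a negative difference. Some of these medians moved without single arrays. Ranges were 0.016 to 0.096 for LXR targets, 0.061 to 0.17 for oxidative phosphorylation, 0.025 to 0.098 for lysosomal genes and 0.070 to 0.23 for Toll-like receptors, whose calls were not all kept. The interferon-stimulated difference ran from 0.087 without Basal_24h replicate 2 to 0.49 without Basal_24h replicate 1.

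Among the genes named here, 77 had a difference past the threshold. The effect of HRG was higher at 24 h, with the log2 difference in brackets, for Ifitm6 (2.13), C1qc (1.78), Cd3g (1.48), Adgre4 (1.48), Mrgprb2 (1.45), Scd1 (1.44), C1qa (1.36), Sparc (1.32), Vsig4 (1.31) and H2-Aa (1.30). It was also higher at 24 h for Fam171b (1.27), Jchain (1.26), Spib (1.24), Serpinb10 (1.23), Timp3 (1.23), Cd83 (1.23), Cpa3 (1.22), Cd79a (1.20), Fabp5 (1.20) and Mrc1 (1.19). Smaller positive differences were those of Marcksl1 (1.19), Ms4a1 (1.17), Ebf1 (1.16), Stat4 (1.15), Fabp4 (1.14), Gadd45a (1.14), Ccl22 (1.14), Fcmr (1.10), C1qb (1.10) and Mospd4 (1.10). The remaining positive differences were those of Tnfsf9 (1.05), Mrgprb1 (1.03), Sema7a (1.02), Mmp9 (1.01), Cxcr4 (1.01), Cd74 (0.99), Ticam2 (0.99), Il12b (0.96), Aqp9 (0.95) and Timp1 (0.94). The remaining positive differences were those of Olfml3 (0.94), Trem1 (0.91), Ddit3 (0.90), Cd86 (0.89), Chac1 (0.88), Cd79b (0.87), Dpp4 (0.84), Gpm6a (0.83), Mt2 (0.76) and Timd4 (0.74). The remaining positive differences were those of Ccr7 (0.73), Irf1 (0.72), Fos (0.67), Ly6d (0.66) and Cd80 (0.65). The effect was lower at 24 h for Nqo1 (-2.78), Il1f9 (-2.50), Treml4 (-1.96), Eid3 (-1.88), Pir (-1.77), Slc6a9 (-1.74), Fam13a (-1.72), Lrp8 (-1.67), Abcc4 (-1.65) and Cbr3 (-1.65). It was also lower at 24 h for Akr1b8 (-1.64), Procr (-1.62), Me1 (-1.58), Ephx1 (-1.500), Srxn1 (-1.48), Slc16a9 (-1.47), Gclc (-1.34), Lipa (-1.002), Ednrb (-0.96) and Aox1 (-0.95). Smaller negative differences were those of Alas1 (-0.71) and Mgst2 (-0.71).

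Rows that are paired with no gene symbol or with several were not tested with the genes. In a fit of every row, 9 rows without a symbol and 5 with several passed the threshold for HRG against basal at 6 h, and 70 without a symbol and 49 with several passed at 24 h.

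Many B cell markers were higher with HRG at 24 h, and of 19 markers with a mean above the median of all genes, 17 (89.5%) were higher, 18 were lower with HRG at 6 h and 18 were lower at 24 h than at 6 h without HRG, past the threshold or not. The median of the list lay at the 100th percentile of 10000 random lists of the same size and brightness (95% of them between -0.072 and 0.059), which argues against a shift of rows of that brightness. Random lists hold unrelated genes, so the percentile shows no more than that. The T cell and NK cell list, which was not called at 24 h, lay at percentile 99.87 of its own random lists. A lower share of macrophages would raise alike those markers of all other cells that macrophages lack. The lists were not restricted to such markers. Above the median level of genes, 32 of 40 markers of 4 other cell types were also higher, past the threshold or not. Their pooled median was 0.32 (bootstrap 95% interval over genes 0.18 to 0.38). B cell markers exceeded them by 0.20 (interval 0.023 to 0.45), with intervals of 0.074 to 0.63 against T cell and NK cell markers, 0.12 to 0.65 against mesothelial, fibroblast and endothelial markers, -0.20 to 0.53 against mast cell and granulocyte markers and -0.050 to 0.36 against dendritic cell markers. These intervals resample genes and hold no spread between samples, and those against mast cell and granulocyte markers and dendritic cell markers include 0. They therefore cannot decide whether a lower share of macrophages was the whole cause. Such a share stays open, as the whole cause or a part, since the other markers were mostly higher too. A larger share of B cells in the HRG samples at 24 h stays open and may also account for part of the antigen presentation genes, since Cd79a was at 8.87 ± 0.31 without and 9.85 ± 0.34 with HRG and Ms4a1 at 8.42 ± 0.31 and 9.23 ± 0.28, and 0 of the 24 markers are on another list. Whether a changed share came from survival of B cells with HRG or from unequal numbers carried into the cultures was not tested.

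Genes that changed with time without HRG differed with it, which a general slowing of the change from 6 h to 24 h could produce. Genes were picked where the mean of the changes with and without HRG, on 1 replicate of each group, exceeded 1 in size, and were measured on the other replicate. For genes that rose, the change with HRG over that without it was 1.26 (95% bootstrap interval 1.09 to 1.47) and 1.29. That rule lets in genes that rose mainly with HRG and drops genes whose rise HRG stopped. The ratio therefore cannot decide whether rises seen without HRG were slowed. For genes that fell, the ratio was 0.759 (interval 0.683 to 0.841) and 0.638, so that a smaller fall with HRG stays open for them, as does an effect of HRG on the falling genes themselves.

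Some interferon-stimulated and inflammatory transcripts were higher with HRG at 24 h. From 6 h to 24 h the interferon-stimulated list fell in both conditions. Without HRG 26 of 32 genes fell (median -0.82), and with HRG 15 fell and 0 rose (median -0.51). The higher level of that list at 24 h thus went with a smaller fall over time. Endotoxin in the recombinant protein could raise both kinds of transcripts. The inflammatory list had a median of -0.12 at 6 h (bootstrap 95% interval over genes -0.27 to -0.0038), with 6 genes that fell and 0 that rose. Its camera call was lost with an estimated correlation (adjusted p = 0.43). The interferon-stimulated list went the other way at 6 h, with a median of 0.14 and 0 genes past the threshold. Without HRG, the inflammatory list was already at median levels of 9.38 and 9.14 on the 6 h arrays, against 7.42 and 7.50 for all genes. Those levels lay under the highest values of the same arrays (14.38 and 14.43), so a ceiling of the arrays does not explain the lack of a rise. A further rise may still not show in such cultures, and the interferon-stimulated list went the other way. These values therefore cannot decide on endotoxin. An earlier, passing rise was not measured. The spread of the arrays differed, and with the lower quartile of each array as a covariate the interferon-stimulated list kept a median of 0.44 at 24 h against 0.40 without it. The lower quartiles at 24 h overlapped between basal (6.00 and 5.92) and HRG samples (5.89 and 5.96). The covariate thus had little room to change that median and is a weak test of the spread as a cause. An effect of HRG on these genes stays open, as does a difference between the cultures, since the median was 0.25 without Basal_24h replicate 2 and 0.63 without Basal_24h replicate 1, and the list call was lost with an estimated correlation (adjusted p = 0.15).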

How the results depend on the processing

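Of 300 results for named genes past the threshold, 179 stayed past it with the same direction under every alternative that gave a value, and none of them changed sign. The covariate for the lower quartile of each array was chosen after seeing the data, and all other settings before. RMA values carry no detection call, so signal over background limits dim genes: the dimmest 30% lay under 6.45 (log2), with 7 of the 172 genes named here: Cd163, Hrg, Ifnb1, Jchain, Pgf, Tnfsf4 and Vegfd. Where an array was left out, the lone array of its group was assumed to vary like the other groups.

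The deviations of same-numbered arrays correlated at -0.33, 0.27, 0.41, -0.28, -0.20 and 0.24 over the 6 pairs of groups. All pairs with Basal_24h were negative and all others positive, so the deviations shared a pattern across groups. The lower quartiles split likewise: replicate 1 was below replicate 2 in Basal_6h (5.85 and 5.99), HRG_6h (5.94 and 5.98) and HRG_24h (5.89 and 5.96). In Basal_24h it was above (6.00 and 5.92). A block on the replicate number cannot fully remove such a pattern. With the replicate number as a block, 82 genes were higher and 160 lower at 6 h, 510 and 215 at 24 h, and 261 and 101 for the difference, with other calls for 3 of 491 single results.

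Counts of genes higher and lower, are given where they moved by over 1.5 times, and the cause was not tested. With trend and robust eBayes they were 180 and 312 at 6 h and 392 and 155 for the difference. Renewed quantile normalization gave 164 higher at 6 h and 876 lower over time with HRG. Testing every row gave 45 and 89 at 6 h, 105 higher for the difference, and r = 0.0637 between the effects at 6 h and 24 h. Asking for 1.5-fold as well left 50 and 83 at 6 h, 269 and 125 at 24 h, 297 and 544 over time without HRG, and 367 and 221 with it. A fit on only the 4 arrays compared gave 97 lower at 6 h and 911 lower over time with HRG. The covariate gave 228 and 290 at 6 h, 453 lower at 24 h, 215 lower for the difference, 1149 higher over time without HRG and 1257 lower with it. Over genes past the threshold at either time, the correlation was 0.276. With an estimated correlation, camera called 0 lists in each comparison, and fry called 0 at 6 h, 13 for the difference and 8 over time with HRG.

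Leaving out each array in turn gave 10 to 103 genes higher and 11 to 184 lower at 6 h, 110 to 536 and 72 to 252 at 24 h, 28 to 265 and 28 to 139 for the difference, 373 to 684 and 600 to 1133 over time without HRG, 390 to 985 and 139 to 695 with it, and r from 0.037 to 0.157.

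Directions turned only for genes or lists near 0. At 6 h, leaving out arrays moved Hrg over -0.150 to 0.0880, Vegfa over -0.0410 to 0.148, Il10 over -0.319 to 0.210, Ifnb1 over -0.0286 to 0.220 and Thbs1 over -0.0615 to 0.0166, and Il10 was 0.13 with the covariate. At 24 h it moved Hrg over -0.225 to 0.00407, Vegfa over -0.000875 to 0.106, Tnf over -0.225 to 0.177, Hmox1 over -0.186 to 0.00430 and Mt1 over -0.0121 to 0.210, and Vegfa was -0.00066 after renewed quantile normalization. None of these genes passed the threshold. Of 38 list calls for HRG at 6 h or 24 h, 25 were kept without each single array. The immediate early list, called up at 24 h, had medians from 0.0407 to 0.115 without single arrays, and its test pointed down without Basal_24h replicate 1 (median 0.041, adjusted p = 0.93).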

Other observations

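Lists in this part were chosen only after the results were seen, so their counts describe these samples and do not test them. Several of the largest decreases at 6 h were in targets of ATF4, the transcription factor of the amino acid and integrated stress response. In a list of such targets, 21 of 45 measured genes fell with HRG at 6 h and 0 rose (median -0.44). Leaving out those among the 12 largest decreases, 15 of 39 fell. Examples are the folate enzyme Mthfd2 (-0.86 ± 0.12), the amino acid transporter Slc7a1 (-0.93 ± 0.14) and the tRNA synthetase Yars (-0.86 ± 0.12), all named after their values were seen. The same list held 29 genes that fell from 6 h to 24 h without HRG and 1 that rose, and 8 that fell with HRG at 24 h.

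Some genes of the NRF2 programme beyond the fixed list fell at 24 h as well. Of 30 further targets, 12 fell with HRG at 24 h and 0 rose (median -0.23), and 17 rose from 6 h to 24 h without HRG while 0 fell. Leaving out those among the 12 largest decreases, 6 of 24 fell at 24 h (median -0.11), among them the transporter Abcc4 (-1.06 ± 0.14), the aldehyde oxidase Aox1 (-0.80 ± 0.10) and the glutathione transferase Mgst2 (-0.71 ± 0.090), named after their values were seen. At 6 h, 1 of the 30 rose and 0 fell. Nqo1 was at 9.18 ± 0.27 (mean log2 level ± SD, n = 2) without HRG at 6 h, 9.55 ± 0.058 with it, 11.18 ± 0.35 without it at 24 h and 8.76 ± 0.083 with it, so that the rise over time seen without HRG was 1.99 ± 0.16 and the change with HRG was -0.79 ± 0.16 (adjusted p = 0.011).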
